A study of Mus musculus with 22 samples.

How the data were processed

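Total RNA of mouse cortex at embryonic day 16 was measured in 6 embryos, 3 labelled wild type and 3 labelled Phf21a knockout, with sex balanced between genotypes per the labels, which do not give the sex of each embryo. Per the labels' protocols, ribosomal RNA was removed from 375 ng of total RNA, stranded libraries were made by the dUTP method and paired-end reads of 150 nt were sequenced. Samples were grouped by the genotype in the labels, and each library is 1 embryo. The 16 CUT&RUN samples of the series were not analysed here.

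The deposited count table holds whole-number read counts per gene, not normalized, for 53640 gene identifiers. The submitters' processing notes list FastQC 0.11.8, STAR 2.6.1, featureCounts, Subread 1.5.0 and DESeq2 1.24.0 and the mm10 genome build; the roles and order of these tools, the strand setting of the counting and the annotation are not given in the sources used here, so genes that overlap another gene or its antisense partner are uncertain, as are near-identical copies. Another 6 columns of the table match no sample of the series and were not used. The authors' deposited comparison table gives log2 fold changes (which by their values appear to be shrunken toward 0), p-values with adjusted p-values, and a mean signal per gene, which equals the mean of the 6 libraries' counts divided by DESeq2 size factors to within a relative 4.96e-15. Symbols were found for 99.8% of the identifiers, and positions from RefSeq on GRCm38, the assembly that mm10 denotes, for 81.7% of tested genes. Counts of the 37 mitochondrially encoded genes are 0 in all 6 libraries. Library totals ranged from 18109863 to 22812607 counts. Over all 15 pairs, counts of 2 libraries differed by a chi-square of 5.54 to 17.4 per degree of freedom, so none looked like a repeat of another. The lowest value was between genotypes, for wild-type replicate 2 and knockout replicate 1. Wild-type replicate 2 gave 8.98 and 9.56 with knockout replicates 2 and 3, against 10.2 and 13.6 with wild-type replicates 1 and 3. Wild-type replicates 1 and 3 differed least from each other (9.03).

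Genes were filtered by edgeR's filterByExpr per genotype, leaving 21822, scaled by TMM and tested with edgeR 4.0.16 (glmQLFit and glmQLFTest at the defaults of that version, design of genotype alone, 4 residual degrees of freedom) in R 4.3.3; p-values were adjusted by Benjamini-Hochberg and called at 0.05. The SE of a log2 fold change is its size divided by the square root of the F statistic. CPM are counts relative to the TMM-scaled library total, computed here from the deposited counts. In total 48 gene lists (18 of cell type markers) were fixed before the data were examined, and the 46 with at least 5 tested members were tested with limma 3.58.1 camera at a preset correlation of 0.01 on log2 CPM with a prior count of 2, beside camera with an estimated correlation and fry. Changed genes within 10 Mb of Phf21a were compared with other genes by Fisher's exact test. Counts were simulated from these libraries' means and sizes for the same comparison, with 200 changed among 21494 tested genes. The changed genes were drawn only from those with a mean of at least 1 CPM. The test recovered 10% of 1.25-fold, 48% of 1.5-fold, 76% of 2-fold and 98% of 3-fold changes, and called 6 unchanged genes. Recovery at lower levels was not simulated. A list lowered by 0.2 on the log2 scale was recovered and 0 other lists were called, with genes simulated as independent.

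Genes were named by a rule written before the data were examined. It takes Phf21a; the 12 largest rises and 12 largest falls among called genes whose libraries do not overlap between genotypes, with a mean of at least 1 CPM in the higher genotype and leaving out predicted gene models; up to 4 called members of each list with the smallest p, or up to 2 members with the highest CPM where none was called; and the 5 called genes with the highest CPM by the same exclusions as the largest changes. The alternatives tried were other scaling factors, filters, tests (DESeq2 1.42.0, limma-voom and robust moderation) and thresholds, each library left out, the replicate number as a block, a per-library loess correction on gene span with and without that block, and leaving out abundant or sex-linked genes. No genome sequence was used here, so the correction leaves out GC content, and transcript length was not used here either. Added after seeing the data were bias-adjusted deviances in edgeR, fits without 2 libraries at a time and a fit with the log2 share of Rn7sk as a covariate.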

Results

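RNA-seq was used to ask how loss of Phf21a, which encodes a histone H3 reader (BHC80) of the LSD1 demethylase complex, alters transcript levels in the embryonic mouse cortex. Gene counts were available for 6 cortices of embryonic day 16, with 3 embryos labelled wild type and 3 labelled homozygous Phf21a knockout, and each library came from 1 embryo. Total counts per library ranged from 18109863 to 22812607. Levels are given as CPM (counts relative to the library total, after scaling between libraries), as mean ± SD over 3 libraries, and fold changes are libraries labelled knockout relative to libraries labelled wild type. The series also holds 16 CUT&RUN samples (antibodies against H3K4me2, H3K9me2 and H4K20me2, with IgG as control), which were not analysed here.

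The targeted gene was measured first as a check of the labels. Phf21a (ENSMUSG00000058318, chromosome 2, 92183751 to 92364667 in GRCm38) was higher, not lower, in the libraries labelled knockout. Its level was 122, 120 and 115 CPM in the wild-type libraries and 165, 174 and 171 CPM in the libraries labelled knockout, a 1.43-fold rise (log2 fold change 0.51, SE 0.055, edgeR quasi-likelihood adjusted p = 0.00768). Gene counts sum all exons, so transcripts that run past a deleted part of the gene stay counted, and the value does not test the allele. The titles of the RNA samples put a c before both genotypes (cKO and cWT), while the genotype label says knockout and the protocol gives Phf21a-/-. What the c stands for is not given. Because the count does not settle whether the labels are right, all directions below are those of the libraries labelled knockout. Gm13786, a transcribed pseudogene lying within the Phf21a span and singled out after its values were seen, rose from 2.22 ± 0.558 to 5.98 ± 0.879 CPM (log2 fold change 1.42, SE 0.20, edgeR quasi-likelihood adjusted p = 0.0419). Gm13785, also within the span and on the same footing, had 2.19 ± 0.833 and 5.32 ± 0.284 CPM and passed in DESeq2 (adjusted p = 8.64e-04) but not in edgeR (quasi-likelihood adjusted p = 0.0664). Reads of these overlapping models and of Phf21a may be shared, so their separate values are uncertain. The Phf21a call was lost without wild-type replicate 3 (edgeR quasi-likelihood adjusted p = 0.0756) and without knockout replicate 3 (0.0868), at log2 fold changes of 0.49 and 0.51.

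**Figure D1:**
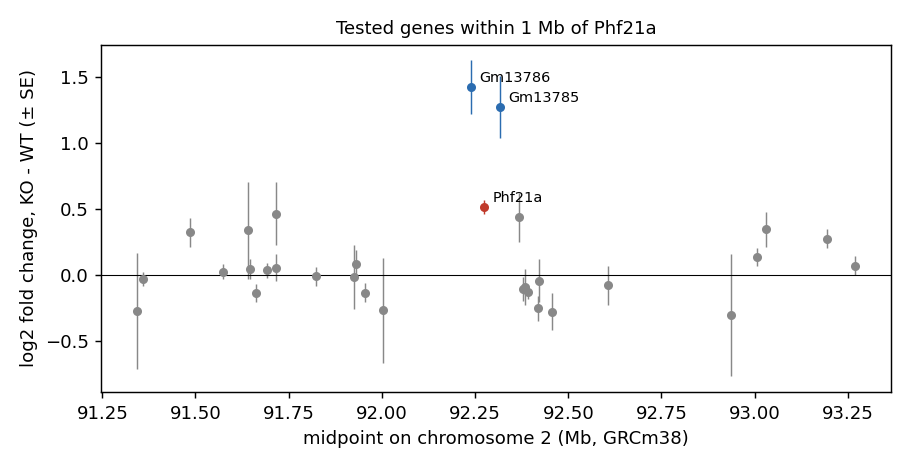
Log2 fold change (libraries labelled knockout minus wild type, bars are the SE) of the tested genes within 1 Mb of Phf21a, plotted at each gene's midpoint on chromosome 2 in GRCm38. Phf21a (red, 0.51) and the pseudogene models within its span (blue, 1.42 and 1.27) lie above the 28 other genes' median of -0.01.

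Phf21b, the closest relative of Phf21a, was among the genes that rose in the libraries labelled knockout. It rose 1.53-fold, from 72.5 ± 2.44 to 111 ± 3.19 CPM (edgeR quasi-likelihood adjusted p = 0.00638). The TEAD transcription factor genes Tead3 and Tead2, whose proteins act in the Hippo pathway, rose 1.97-fold (10.3 ± 0.456 to 20.3 ± 1.53 CPM) and 1.55-fold (55.1 ± 5.23 to 85.1 ± 9.06 CPM). Phldb2, which encodes a cortical microtubule-anchoring protein, rose 1.69-fold (18.1 ± 0.713 to 30.6 ± 0.953 CPM). L3mbtl3, which encodes a methyl-lysine reader, rose 1.55-fold (75.4 ± 3.04 to 117 ± 10.3 CPM), and the zinc finger genes Plag1 and Zfp516 rose 1.62-fold and 1.59-fold. The non-muscle myosin gene Myh14 rose 2.07-fold at a low level (2.99 ± 0.54 to 6.17 ± 0.716 CPM). Cast, the inhibitor of calpain proteases, rose 1.78-fold, Lrig3 1.77-fold, the protease gene Adamts4 1.63-fold, the protein kinase C gene Prkcd 1.61-fold and the ectonucleotidase gene Entpd1 1.59-fold. Among the most abundant genes that changed, predicted gene models left out, the T-type calcium channel gene Cacna1g rose 1.37-fold (104 ± 8.49 to 142 ± 10.3 CPM) and Mpdz rose 1.30-fold (88.9 ± 2.44 to 116 ± 4.48 CPM). In the edgeR quasi-likelihood test adjusted p was 0.00638 for Tead3 and Phldb2, 0.0116 for L3mbtl3 and Zfp516, 0.0168 for Prkcd and 0.0432 for Tead2. It was 0.0481 to 0.0489, close to the threshold, for Myh14, Cast, Lrig3, Adamts4, Plag1, Entpd1, Cacna1g and Mpdz. Phf21b, Tead3 and Phldb2 were the 3 genes called in each of the 6 fits that left out 1 library.

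Other genes fell. Grin1, the obligatory subunit of NMDA receptors, fell to 0.695 of the wild-type level (57.6 ± 4.17 to 40.1 ± 3.62 CPM). Scn2a, an early sodium channel of the axon initial segment, fell to 0.73 (190 ± 4.95 to 139 ± 14.3 CPM), and Sptbn4, the spectrin of the same membrane domain, fell to 0.664. The pacemaker channel gene Hcn2 fell to 0.602 (15.8 ± 0.563 to 9.51 ± 0.825 CPM) and the neuronal pentraxin receptor gene Nptxr to 0.563 (69.8 ± 10.3 to 39.4 ± 7.06 CPM). The ion exchanger genes Slc24a3 and Slc9a7 fell to 0.632 and 0.631, the small GTPase regulators Adap1 and Dock9 to 0.611 and 0.718, the copine gene Cpne7 to 0.509, and the clustered protocadherin Pcdhgc4 to 0.74. Xlr4a, an X-linked gene with near-identical neighbouring copies between which reads could be split, had 53, 27 and 33 counts in the wild-type libraries and 0, 1 and 7 in the libraries labelled knockout (edgeR quasi-likelihood adjusted p = 0.0481). Adjusted p of all genes named in the present paragraph lay between 0.0298 (Adap1) and 0.0486 (Slc24a3, Slc9a7 and Sptbn4) in the edgeR quasi-likelihood test, and each lost its call without at least 1 of the 6 libraries.

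**Figure D2:**
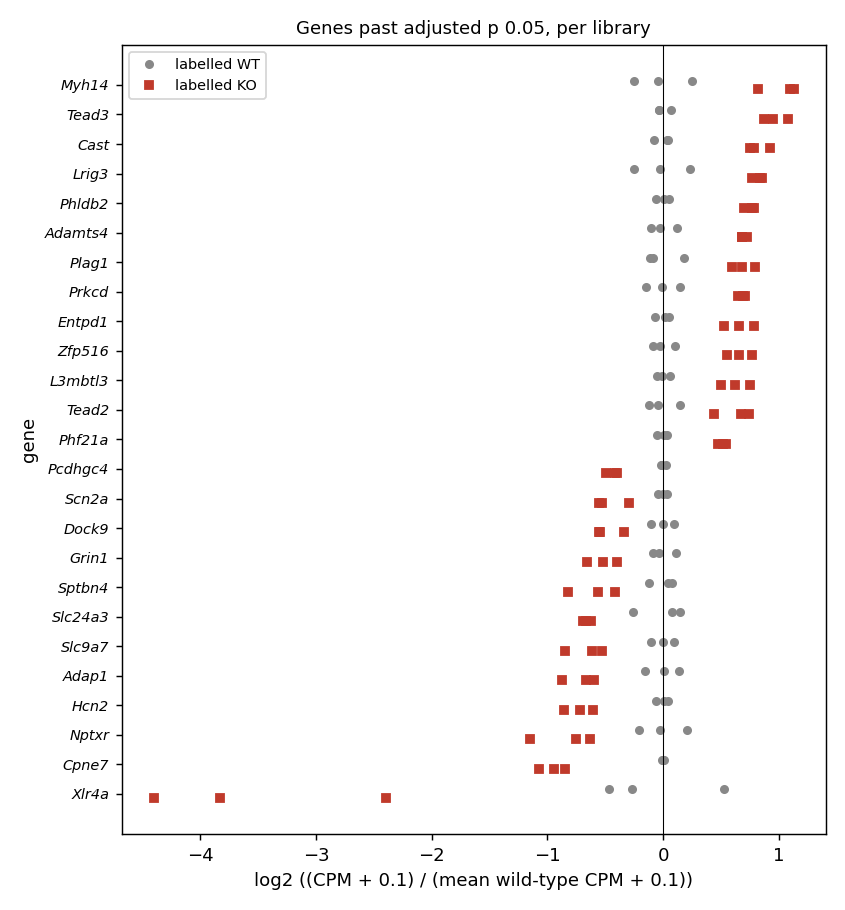
Each point is 1 library, grey circles wild type and red squares labelled knockout, as log2 of CPM plus 0.1 over the mean wild-type CPM plus 0.1. Genes other than Phf21a were picked among those whose 3 libraries labelled knockout lie on one side of the 3 wild-type libraries, so their separation is by construction. Phf21a was shown whatever its values, and its libraries labelled knockout lie above.

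In all, 39 of 21822 genes tested passed an adjusted p of 0.05 in the edgeR quasi-likelihood test, 23 higher and 16 lower in the libraries labelled knockout, including 3 predicted gene models. Changes were small: 15 of the 39 were under 1.5-fold and 3 were at least 2-fold. All 39 had non-overlapping libraries, as did 18.2% of all tested genes, against 10% by chance, and 2977 genes had an unadjusted p under 0.05 where 1091 would by chance. The authors' deposited table lists 393 genes at an adjusted p under 0.05, 146 higher and 247 lower, 38 of which are among the 39. DESeq2 run here on the same counts gave the same numbers and the same p-values for named genes, so it repeats the authors' test. It gave an adjusted p to 14021 genes and none to Xlr4a. The edgeR count of 39 moved with every library: it was 8 without wild-type replicate 1, 573 without wild-type replicate 2, 4 without wild-type replicate 3, 9 without knockout replicate 1, 5 without knockout replicate 2 and 4 without knockout replicate 3. It was 856 with no low-count filter, 108 with robust moderation, 9 at a mean CPM of at least 1, and the split of higher to lower calls was 20 to 7 with upper-quartile scaling and 21 to 4 with total counts only. Without knockout replicate 2 and wild-type replicate 1 together, which carried markers of neighbouring tissue (a setting chosen after seeing the data), it was 0 in the edgeR quasi-likelihood test, with 1916 genes at an unadjusted p under 0.05 and 28 called by DESeq2.

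Members of the LSD1-CoREST complex and its partners leaned higher. Here and below, members of a list that pass over all genes are those of the edgeR quasi-likelihood test unless DESeq2 is named. Of 23 tested members 2 rose over all genes, Phf21b and Zfp516, 0 fell (10 at an unadjusted p under 0.05 in either direction) and 21 did not pass. Adjusted over the list alone 7 rose and 0 fell, and DESeq2 called 4 higher and 0 lower. The list's median log2 fold change was 0.10, and its scores in the libraries labelled knockout, 0.076, 0.076 and 0.11, lay above those of the wild-type libraries, -0.081, -0.059 and -0.13 (mean log2 CPM relative to each gene's mean). Scores did not overlap for 9 of all 46 lists tested, where 10% would by chance. The LSD1-CoREST list passed limma camera with a preset correlation (adjusted p = 6.55e-05) and did not with an estimated correlation (adjusted p = 0.599 with an estimated correlation, unadjusted 0.015). Kdm7a, a demethylase of H3K9 and H3K27, rose 1.39-fold (62.7 ± 4.98 to 86.9 ± 6.18 CPM; edgeR quasi-likelihood adjusted p = 0.0486) and was the only one of 26 H3K9 and H4K20 methylation enzymes to pass, in edgeR as in DESeq2; that list did not pass camera (adjusted p = 0.0704). None of 24 H3K4 methylation enzymes passed in edgeR or DESeq2 (4 at an unadjusted edgeR p under 0.05), and that list's camera adjusted p was 0.666; Kdm5b had 337 ± 15.7 and 384 ± 17.0 CPM.

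Lists of neuronal function leaned lower. Of 46 postsynaptic genes 2 fell (Grin1 and Nptxr) and 44 did not pass, with 10 falling when adjusted over the list alone and a median log2 fold change of -0.16. Of 43 REST-regulated genes 2 fell (Grin1 and Scn2a) and 41 did not pass, with 19 falling when adjusted over the list alone and a median of -0.19. None of 39 presynaptic genes passed over all genes in edgeR (23 at an unadjusted p under 0.05), with 21 falling and 2 rising when adjusted over the list alone and a median of -0.18; Nrxn1 had 426 ± 15.7 and 376 ± 21 CPM. Of 37 voltage-gated ion channels Scn2a and Hcn2 fell, Cacna1g rose and 34 did not pass, with 14 falling and 1 rising when adjusted over the list alone and a median of -0.13. DESeq2 called 9 postsynaptic, 10 REST-regulated, 9 presynaptic and 7 channel genes lower, and 1 channel gene higher. These lists share members. All 4 passed camera with the preset correlation (adjusted p from 4.98e-08 for postsynaptic genes to 1.40e-04 for channels) and did not with an estimated correlation (adjusted p = 0.599 with an estimated correlation for each). Library scores did not overlap between the genotypes for 3 of the 4, which share members, against 9 of all 46 lists tested. For REST-regulated genes wild-type replicate 2 (-0.081) lay below knockout replicates 1 and 2 (-0.040 and -0.055). Library composition differed along with these scores, as noticed after the values were seen. Rn7sk made up 1.05, 0.529 and 0.935% of counts in the wild-type libraries and 0.587, 0.705 and 0.462% in those labelled knockout, and Gm26917 made up 1.70, 2.15 and 1.49% and 2.00, 2.29 and 2.26%. The mean score of the 4 lists together was 0.11, -0.015 and 0.13 in wild type and -0.021, -0.068 and -0.14 in libraries labelled knockout, a correlation of 0.876 with the log2 share of Rn7sk.

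Genes of cell division and intermediate progenitors, the dividing cells that give rise to cortical neurons, leaned higher without any member passing over all genes in the edgeR quasi-likelihood test (18 G2/M, 10 S phase, 20 histone and 8 progenitor genes at an unadjusted p under 0.05). DESeq2 called 2 histone and 4 progenitor genes higher and 0 genes of the other 2 lists. Of 30 G2/M genes 8 rose when adjusted over the list alone (median log2 fold change 0.25), of 30 replication and S phase genes 2 rose (median 0.16), and of 60 replication-dependent histone genes none did (median 0.32). Top2a, needed for chromosome separation, had 241 ± 28.6 and 293 ± 27.1 CPM. Of 15 intermediate progenitor markers 6 rose when adjusted over the list alone (median 0.23), while Eomes, their best known marker, had 76.0 ± 19.9 and 81.6 ± 12.7 CPM. All 4 lists passed camera with the preset correlation (adjusted p = 1.37e-08, 3.23e-05, 7.39e-09 and 1.32e-04) and none did with an estimated correlation (adjusted p = 0.599 with an estimated correlation for each). The genotypes overlapped in all 4 list scores, since wild-type replicate 2 lay above knockout replicate 1. Wild-type replicates 1 and 3, with the 2 highest shares of Rn7sk, had the 2 lowest scores in each, and the score of the 4 lists together had a correlation of -0.697 with the log2 share of Rn7sk. The histone genes were highest in knockout replicate 2 (score 0.47 against 0.044 or below in the other libraries labelled knockout).

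**Figure D3:**
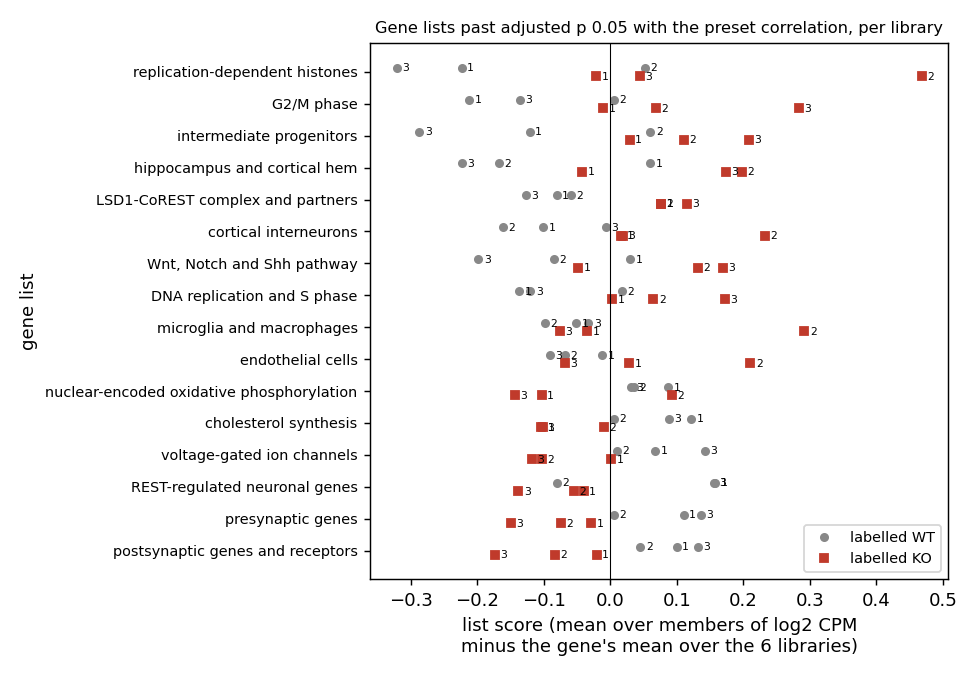
Score of each gene list per library, the mean over members of log2 CPM minus the gene's mean over the 6 libraries, for 16 lists that passed camera with the preset correlation (choroid plexus is left out, as knockout replicate 2 scores 2.10); numbers are replicates. The genotypes are apart for postsynaptic and presynaptic genes, channels, cholesterol synthesis, LSD1-CoREST members and interneurons, and overlap for the other lists shown. Over all 46 lists tested they are apart for 9.

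Markers of other cells also differed between libraries. Cortical interneuron markers had a median log2 fold change of 0.18, none of 22 passed over all genes in edgeR (6 at an unadjusted p under 0.05) and 5 rose when adjusted over the list alone; Dlx1 had 187 ± 13.8 and 246 ± 30.4 CPM and passed in DESeq2 alone (adjusted p = 0.00355). The choroid plexus list had the largest median, 1.17, and rested on knockout replicate 2, which held Ttr at 784 CPM against 1.22 to 6.91 CPM elsewhere; without that library the median was 0.11. Microglia (median 0.11; Csf1r 10.8 ± 0.165 and 13.4 ± 1.17 CPM) and endothelial cells (0.15) were likewise highest in knockout replicate 2, with scores of 0.29 and 0.21. Without knockout replicate 2 the camera adjusted p was 0.704 for choroid plexus, 0.451 for microglia and 0.257 for endothelial cells; without that library and wild-type replicate 1 it was 0.0946 for interneurons. Hippocampus and cortical hem markers had a median of 0.23 and Wnt, Notch and Shh pathway genes 0.17. Cholesterol synthesis genes (median -0.14, Hmgcs1 451 ± 28.6 and 397 ± 29.3 CPM) and nuclear-encoded oxidative phosphorylation genes (-0.07) leaned lower. Oxidative phosphorylation scored highest of all in knockout replicate 2 (0.093, against 0.087 or below in wild type). Its lean rested on knockout replicates 1 and 3 (-0.10 and -0.14). In these 8 lists no member passed over all genes in edgeR (3 to 14 per list at an unadjusted p under 0.05), and DESeq2 called 1 interneuron, 1 hippocampal and 2 Wnt, Notch and Shh pathway genes higher and 1 cholesterol and 5 oxidative phosphorylation genes lower. All 8 passed camera with the preset correlation (adjusted p from 9.87e-05 to 0.0491), and adjusted p was 0.599 for 6 and 0.746 for choroid plexus and oxidative phosphorylation with an estimated correlation. Knockout replicate 2 and wild-type replicate 1 also held most RNA of the diencephalic marker Tcf7l2 (78.8 and 128.9 CPM, against 9.86 to 28.5 CPM in the other libraries).

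Other cell types and programmes did not pass camera. Among them were radial glia (median log2 fold change 0.14, adjusted p = 0.175), immature neurons (-0.13, 0.0573), upper-layer neurons (-0.05, 0.57), deep-layer neurons (0.03 although the test pointed down, 0.977), astrocytes (-0.06, 0.524), oligodendrocyte lineage (-0.02, 0.751) and heat shock genes (-0.10, 0.0597), with adjusted p from limma camera with the preset correlation. Of 49 autism and intellectual disability genes Scn2a fell (camera adjusted p = 0.0715), and of 56 clustered protocadherins Pcdhgc4 fell (0.108). In the edgeR quasi-likelihood test none of 18 germline genes passed (list 0.91; 2 at an unadjusted p under 0.05, 0 by DESeq2), nor any of 25 neuronal splicing regulators (0.595; 9, 2), 51 axon guidance genes (0.666; 12, 1), 86 ribosomal protein genes (0.438; 10, 2) or 20 immediate early genes (0.666; 4, 1). Across all 46 lists tested, 17 passed with the preset correlation, 11 higher and 6 lower, and 0 with an estimated correlation, where 1 list had an unadjusted p under 0.05; fry, which tests each list on its own, called 0 in one direction, with 9 at an unadjusted p under 0.05, and 16 in its test for members changing in either direction, 9 of them among the 17. Regrouping the 6 libraries into other sets of 3 and 3 gave up to 18 lists with the preset correlation.

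Changed genes near Phf21a were counted because an allele can carry linked differences. Of 104 tested genes within 10 Mb of Phf21a, leaving out Phf21a itself, 1 (Gm13786) changed, or 0.962%, against 0.209% of 17714 other genes (Fisher's exact test, two-sided, p = 0.20). Gm13786 lies within the Phf21a span and may share its reads, so no tested gene of the window outside that span changed. The count varied with the setting. It was 0 without wild-type replicate 1 or 3 and without each of the 3 libraries labelled knockout, and 5 without wild-type replicate 2. It was 8 of 189 with no low-count filter, 3 at an adjusted p under 0.10, 2 with robust moderation and 5 of 76 with DESeq2. Gm13786 and Gm13785, both within the Phf21a span, were among those at 0.10 and among those of DESeq2. Of 25 neighbours fixed by name, none passed over all genes in edgeR (6 at an unadjusted p under 0.05), 2 rose when adjusted over the list alone and DESeq2 called 2 higher (median log2 fold change -0.01, limma camera adjusted p = 0.697, and fry in either direction adjusted p = 0.0108); Ckap5 had 441 ± 21.5 and 448 ± 3.16 CPM. Genes are not independent, and counting Phf21a itself gave an exact p of 0.0221.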

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

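The 2 settings that leave out 2 libraries and those with bias-adjusted deviances or the share of Rn7sk as a covariate were chosen after seeing the data; the others were chosen before. Against 39 genes changed (23 higher, 16 lower) in edgeR's quasi-likelihood test, the count was 856 (416 higher, 440 lower) with no low-count filter, where the median prior degrees of freedom of the variances were 65.1 against 7.01. It was 393 (146 higher, 247 lower) with DESeq2, 108 (49, 59) with robust moderation, 27 (20, 7) with upper-quartile factors, 25 (21, 4) with total counts only, 27 (14, 13) with limma-voom and 9 (8, 1) at a mean of at least 1 CPM. By construction it moved with the threshold, to 152 (73, 79) at an adjusted p under 0.10, 4 (4, 0) at 0.01 and 24 (15, 9) when at least 1.5-fold was asked for. It ran from 4 to 573 without 1 library (8 without wild-type replicate 1, 573 without 2, 4 without 3; 9 without knockout replicate 1, 5 without 2, 4 without 3), with 3 to 185 higher and 0 to 388 lower; DESeq2 gave 46 to 881. Without the 2 libraries carrying choroid plexus or meningeal markers it was 0 (0 higher, 0 lower; 1916 at an unadjusted p under 0.05, 28 by DESeq2), and without both Xist-high libraries 2 (0 higher, 2 lower; 1238 at an unadjusted p under 0.05, 15 by DESeq2), neither of them among the 39; both settings leave 2 libraries per genotype. With the log2 share of Rn7sk as a covariate it was 7 (7 higher, 0 lower; 2039 at an unadjusted p under 0.05; DESeq2 was not run with it), 6 of them among the 39; the covariate takes 1 residual degree of freedom. DESeq2 size factors in edgeR (30), the span correction (45), bias-adjusted deviances (37) and leaving out abundant (39) or sex-linked genes (45) kept the counts within 1.5 times. Except where the threshold or the number of libraries sets it, the cause was not tested. All 39 kept their sign throughout, which their non-overlapping libraries largely fix. For 28 other called named genes, 398 of 727 values stayed past the threshold, 329 did not and likewise 0 changed sign. For the 78 not called, 18 of 2017 passed.

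The replicate number did not pair the samples: deviations of same-numbered libraries correlated at -0.20, -0.11 and 0.13, and wild-type replicate 1 correlated best with knockout replicate 2 (0.32). With the number as a block 14 genes changed (11 higher, 3 lower), 10 of them among the 39, and with the block and the span correction 6 (4 higher, 2 lower), all among the 39. The block leaves fewer residual degrees of freedom, and the fewer calls do not show smaller changes.

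Phf21a was higher in every setting. Its log2 fold change was 0.49 to 0.53 without 1 library, and the call was lost without wild-type replicate 3 (adjusted p = 0.0756) and knockout replicate 3 (0.0868). It was also lost with the block and span correction (0.52), at the 1.5-fold minimum, which its change does not reach (0.51), without the 2 libraries carrying other tissue markers (0.51) and without both Xist-high libraries (0.49); the adjusted p over all settings ran from 1.16e-09 (DESeq2) to 0.338 (without both Xist-high libraries). Of the gene lists, 17 passed camera with the preset correlation, 17 with the block and 17 to 23 without 1 library, with 14 to 17 shared, and 27 with the Rn7sk covariate, the 17 among them. Camera with an estimated correlation called 0 (1 at an unadjusted p under 0.05) and fry 0 in one direction (9), all 17 lists pointing the same way in each; fry's test for change in either direction called 16, 9 of them among the 17. Near Phf21a, the excess of changed genes, 0.753 percentage points, was 1.70 with Phf21a counted (Fisher's exact p = 0.0221), the one setting in which it passed. The excess rests on 1 gene. No gene near Phf21a changed, and the excess was -0.04 to -0.02, without wild-type replicate 1 or 3 or any 1 library labelled knockout, against 1.69 (5 genes) without wild-type replicate 2; it was also below 0 with the block (-0.073, and -0.034 with the span correction too), with the Rn7sk covariate (-0.034), at a mean of at least 1 CPM (-0.050) and at an adjusted p under 0.01 (-0.017), and higher at an adjusted p under 0.10 (2.05, 3 genes), with no low-count filter (1.35, 8 of 189 genes), with robust moderation (1.34, 2 genes) and with DESeq2 (3.58, 5 of 76 genes).

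On simulated counts of this depth and number of libraries 48% of 1.5-fold changes were recovered; other depths were not simulated, so what depth alone limits was not tested.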

Other observations

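The tests by the span correction and by regrouping the libraries were set before their results were seen. Those on exchanged labels, the region around Phf21a, the share of neurons and the share of Rn7sk were chosen after, as was leaving out 2 libraries, picked for their markers, although the bound for the neuronal lists was set before that fit. Markers of neighbouring tissues varied between libraries of the same genotype. The list of thalamus and other diencephalon scored 1.21 in wild-type replicate 1 and 0.81 in knockout replicate 2, and -0.07 or below in the other 4 libraries (median log2 fold change -0.10 between genotypes although the test pointed up, limma camera adjusted p = 0.808); its member Lhx9 had 57.2 and 54.9 CPM there and 22.0 to 36.5 CPM in the others. The meningeal list scored 0.86 and 0.34 in the same 2 libraries and 0.08 or below in the others (median -0.34, limma camera adjusted p = 0.568), with Col1a1 at 31.6 and 9.58 CPM there and 4.86 to 19.4 CPM in the others.

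The remaining lists did not pass limma camera with the preset correlation: Cajal-Retzius cells (median log2 fold change 0.16, adjusted p = 0.0597), stress response and unfolded proteins (0.05, 0.0597), erythroid cells (0.11, 0.095), pericytes (0.05, 0.106), ganglionic eminence (0.002, 0.271), p53 targets (0.06, 0.30), interferon-stimulated genes (-0.08, 0.524), hypoxia and glycolysis (0.04, 0.568), transcription factors of other lineages (-0.06, 0.994) and sex-linked genes (0.09 although the test pointed down, 0.994).

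Xist stood at 1898 and 1793 CPM in replicate 3 of the 2 genotypes and at 0.546 to 2.51 CPM in the other 4 libraries, while the Y-linked Kdm5d stood at 0.050 and 0.043 CPM in replicate 3 and at 107 to 121 CPM in the others. The genes that follow were picked after their values were seen, and none passed over all genes in the edgeR quasi-likelihood test, while Xlr3b, Hbb-y and Rest passed in DESeq2 (adjusted p = 2.62e-05, 0.0244 and 0.0114), which gave Xlr3a and Xlr4b no adjusted p. Of the X-linked relatives of Xlr4a, Xlr3b had 13.9, 5.99 and 10.9 CPM in wild type and 3.49, 4.67 and 3.46 CPM in libraries labelled knockout (edgeR quasi-likelihood adjusted p = 0.0744), Xlr4b had 13, 12 and 24 counts against 4, 4 and 0 (0.101), and Xlr3a overlapped between genotypes (0.366). The embryonic globin gene Hbb-y had 5.01, 3.34 and 5.06 CPM in wild type and 6.82, 17.7 and 15.1 CPM in libraries labelled knockout (edgeR quasi-likelihood adjusted p = 0.0762). Rest had 29.1, 28.9 and 26.0 CPM in wild type and 37.2, 35.3 and 37.1 CPM in libraries labelled knockout (log2 fold change 0.38, edgeR quasi-likelihood adjusted p = 0.0762).

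Phf21a counts were higher on average in libraries labelled knockout. The tables argue against labels exchanged between 1 library of each genotype, which would put 1 library of each among the other genotype: the lowest library labelled knockout lies 43.2 CPM above the highest wild-type library and the wider range within a genotype is 8.53 CPM. They also argue against higher output of the whole region, since the 28 other genes within 1 Mb had a median log2 fold change of -0.014 (95% bootstrap interval over genes -0.10 to 0.062), below the bound of 0.256 set from the change of Phf21a itself. An exchange of all labels cannot be told apart, since it would turn the sign of 0.51 and keep its size. The knockout genotype, for example through transcripts that the allele still makes, stays open and was not tested, since the gene counts do not separate exons.

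Genes of synapses and excitability leaned lower, with a median log2 fold change of -0.162 over the 147 tested members of the postsynaptic, presynaptic, REST-regulated and channel lists. The tables argue against a bias by gene span as the whole cause: after a per-library correction on gene span, a small one (median 0.0127, at most 0.118 on the log2 scale), the median was -0.159 (95% bootstrap interval over genes, which are not independent, -0.191 to -0.114), and against choroid plexus or meningeal tissue in 2 libraries, with a median of -0.165 without knockout replicate 2 and wild-type replicate 1 (-0.194 to -0.126). Library composition cannot be told apart. With the log2 share of Rn7sk as a covariate the median was -0.115 (-0.143 to -0.079). The genotype difference in the libraries' mean score went from -0.153 to -0.085, with 3 residual degrees of freedom. In a linear fit of that score, the unadjusted p of genotype was 0.0578 alone and 0.135 beside the share of Rn7sk. Neither passed, so the lean did not pass with libraries rather than genes as the unit. The share itself leaned lower in libraries labelled knockout (correlation with genotype -0.564), but the genotypes overlapped. Wild-type replicate 2 (0.529%) lay below knockout replicates 1 and 2 (0.587 and 0.705%). The intervals are over genes and leave out the spread between embryos. By library the mean score barely separated the genotypes, at -0.015 in wild-type replicate 2 and -0.021 in knockout replicate 1. A lower share of neurons cannot be told apart: the median lay -0.108 from that of 50 immature, upper-layer and deep-layer neuron markers (-0.205 to -0.029), but this difference overlapped between genotypes, at 0.16, -0.12 and 0.13 in wild type and -0.09, 0.02 and -0.10 in libraries labelled knockout. A bias by transcript length, which was not used here, and the knockout genotype stay open and untested.

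Genes of cell division and intermediate progenitors leaned higher, with a median log2 fold change of 0.251 over the 135 tested members of their 4 lists. Library composition cannot be told apart here either. With the log2 share of Rn7sk as a covariate the median was 0.163 (95% bootstrap interval over genes 0.133 to 0.188). The genotype difference in the libraries' mean score went from 0.258 to 0.181, with 3 residual degrees of freedom. In a linear fit of that score, the unadjusted p of genotype was 0.0823 alone and 0.272 beside the share of Rn7sk. Neither passed, so this lean too did not pass with libraries rather than genes as the unit. The interval leaves out the spread between embryos. By library the mean score overlapped between genotypes, at 0.035 in wild-type replicate 2 and -0.008 in knockout replicate 1. The knockout genotype stays open and untested.

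The 6 libraries split into 3 and 3 in 10 ways, too few for a share under 0.05. For genes changed, 1 split, the real one, gave as many as 39, and the highest of the others was 0 in edgeR's quasi-likelihood test (285 to 1688 genes at an unadjusted p under 0.05 against 2977, and 0 to 41 by DESeq2 against 393). For gene lists, 2 splits gave as many as the real 17, and the highest of the others, 18, set wild-type replicates 1 and 3 with knockout replicate 2 against the rest. The 2 libraries with diencephalic markers thus lay on one side. So did the 3 highest shares of Rn7sk (1.05, 0.935 and 0.705% of counts, against 0.462 to 0.587% in the rest). That split cannot tell these differences apart. Without wild-type replicate 1 and knockout replicate 2, 14 lists passed, 13 of them among the 17.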
